A study of Danio rerio with 4 samples.

How the data were processed

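The samples were 4 RNA-seq libraries from Tg(fli1a:egfp) zebrafish embryos at 24 hours post fertilization, 2 from GFP-positive and 2 from GFP-negative sorted cells. Per the labels, fixed embryos were dissociated and sorted, RNA was extracted by the MARIS protocol, which recovers RNA from fixed and sorted cells, and libraries were made from total RNA with the TotalScript kit. The design text gives the purpose as a comparison of cell-type-specific expression with chromatin accessibility (ATAC-seq), which was not analysed here.

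The submitters' processing notes name TopHat2 2.0.9, Cuffdiff 2.1.1 and the Zv9 genome build; alignment and counting settings were not given in the sources used here. The table is a Cuffdiff gene comparison. Per the file headers it gives 1 FPKM value per gene for each group. It was taken as the authors' estimate over both libraries from the sample titles, which the headers do not state. Values of single libraries were not used here. It also holds the deposited log2 ratio, a test statistic (a score with no fixed range), a p-value and a q-value, each as the authors deposited it. The deposited log2 ratio is GFP-negative over GFP-positive, so its sign was turned; it matched the FPKM columns within 1.5e-05. The deposited q-value was checked to be the Benjamini-Hochberg (BH) adjustment of the deposited p-value over tested genes, within 5.3e-07. Of 31716 genes, 7299 had a test, 24304 had too few alignments by the Cuffdiff status and 113 were set aside as LOWDATA. A gene was called when the authors' deposited q was under 0.05. Summed FPKM was 798915 in GFP-positive and 664220 in GFP-negative cells. Numbers of reads were not used here, so the depth is unknown, and no interval or detection limit is given. A value of exactly 0 can be a failed estimate, so such genes are said to be listed at 0 and get no fold. Tested genes at 0 in 1 group have a p-value and a q-value but no test statistic.

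Coordinates are those of the Cuffdiff locus in Zv9 as the file gives them; whether starts count from 0 or 1 is not given there. Overlapping genes share a locus, which concerned 1757 tested genes, 176 of them called. Some gene names occur in more than 1 row, and 3162 rows share a name with another. Each row was kept as a gene.

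The 20 named gene lists, and 2 lists defined by the names of ribosomal protein genes and of mitochondrially encoded genes, were fixed before the data were examined, with the threshold, the tests and the rule for named genes. For each list, members called higher, lower or not were counted over all tested genes, and again with BH over the list alone. Two-sided Fisher's exact tests compared calls in the list with calls in all other tested genes, in each direction, with BH over the 42 tests of the 21 lists with tested genes. The list median of log2((GFP-positive FPKM + 1)/(GFP-negative FPKM + 1)) was placed among 10000 random lists of the same size drawn with replacement within 20 bins of mean expression. This scale understates the change of low genes. Lists share members (15 of the 32 tested pan-endothelial genes are in another list), and genes are not independent, so these tests describe the lists and do not replace replicates. Genes are named by this rule: fli1a, the 12 largest values of log2((FPKM + 1) ratio) in each direction among called genes of at least 1 FPKM in the higher group, up to 4 called members of each list in its main direction and up to 2 in the other, all called members of lists with 5 or fewer, and a fixed set of best known markers that may be named when not called. Not every gene that the rule allows is named. In a group of genes chosen after the values were seen, 1 gene was left out and is not reported here.

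Members going the other way were counted in 8 lists with calls in 1 direction only. They were 4 lists higher in GFP-positive cells (pan-endothelial, transcription factor, erythroid, myeloid) and 4 lower (neural, skeletal muscle, notochord, pigment). In them, 0 members went the other way at p under 0.05 without adjustment in the authors' deposited table. The cell cycle list, with 1 gene called higher and 0 lower, was not in this count. Alternatives tried were a q of 0.01, a minimum log2 ratio of 1, minimum values of 1 and 5 FPKM, BH again over genes of at least 1 FPKM, gene names that occur once, ratios centred on the median over 11895 genes of at least 1 FPKM in both groups (0.01), genes at 0 left out, pseudocounts of 0.1 and 0.01, first symbols of each list alone and random lists not matched. Further alternatives were chosen after seeing the data: genes alone in their locus and list symbols matched through a reference of gene names, either by its names alone or by its names or those of the table. Of 21422 gene IDs with a name in that reference, 13259 are spelled otherwise than in the table, often as the human symbol (FLI1 for fli1a), so matching by its names alone drops members by spelling.

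The code was tested on simulated data with a fixed seed. For a simulated GFP-positive against GFP-negative comparison of 7299 genes, a planted list of 30 genes with 20 raised had its median at percentile 100 and a Fisher's exact p = 1.2e-26. Of 200 lists of unchanged genes, 3% fell below percentile 2.5 or above percentile 97.5 of random lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.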

Results

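RNA was measured in cells sorted from zebrafish embryos at 24 hours post fertilization. The embryos carried the Tg(fli1a:egfp) transgene, in which regulatory sequence of the fli1a gene drives a green fluorescent protein (GFP). The labels use it to mark endothelial cells, the cells that line blood vessels. The gene lists were fixed on the view that it can also mark blood, cranial neural crest and pharyngeal arch cells. Fixed, dissociated embryos were separated by fluorescence-activated cell sorting into a GFP-positive fraction, labelled as endothelial cells, and a GFP-negative fraction, labelled as non-endothelial cells. Each fraction gave 2 RNA-seq libraries, 4 in all. The expression table held 31716 genes with 1 FPKM value (mapped fragments per gene, scaled by transcript length and library size) per gene and fraction. Values of the separate libraries were not used here, so each level below is the authors' group value, with no standard deviation. The depth of the libraries is unknown. The labels do not say whether the libraries of a fraction came from separate clutches of embryos. The p-values therefore refer to these libraries alone, and differences between the libraries of a fraction may be technical. How far the p-values reflect such differences cannot be read from 1 value per gene and fraction.

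The comparison between the fractions asked which genes distinguish fli1a:egfp-expressing cells from the rest of the embryo. Called higher in the GFP-positive fraction were 18 of 32 pan-endothelial, 22 of 24 erythroid and 8 of 20 myeloid genes, while arterial and Notch pathway genes went both ways. Called lower were 24 of 33 neural, 28 of 35 skeletal muscle, 6 of 9 notochord, 12 of 24 epidermal and 6 of 11 pigment cell genes, with 2 epidermal genes called higher. In all, 7299 genes were tested in the authors' deposited table, and 1046 passed a q-value threshold of 0.05, which is 14.3% of the tested genes. Of these, 524 were higher and 522 were lower in GFP-positive cells. Among called genes with values above 0 in both fractions, the median fold in the authors' deposited table was 4.42 for genes higher in GFP-positive cells and 5.66 for genes lower in them. A further 42 genes called higher were listed at 0 in GFP-negative cells, and 23 genes called lower were listed at 0 in GFP-positive cells. The smallest p in the authors' deposited table was 5e-05, shared by 381 called genes, and it corresponds to a q of 0.000958. At a stricter q of 0.01 the authors' deposited table called 630 genes, 301 higher and 329 lower.

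**Figure D1:**
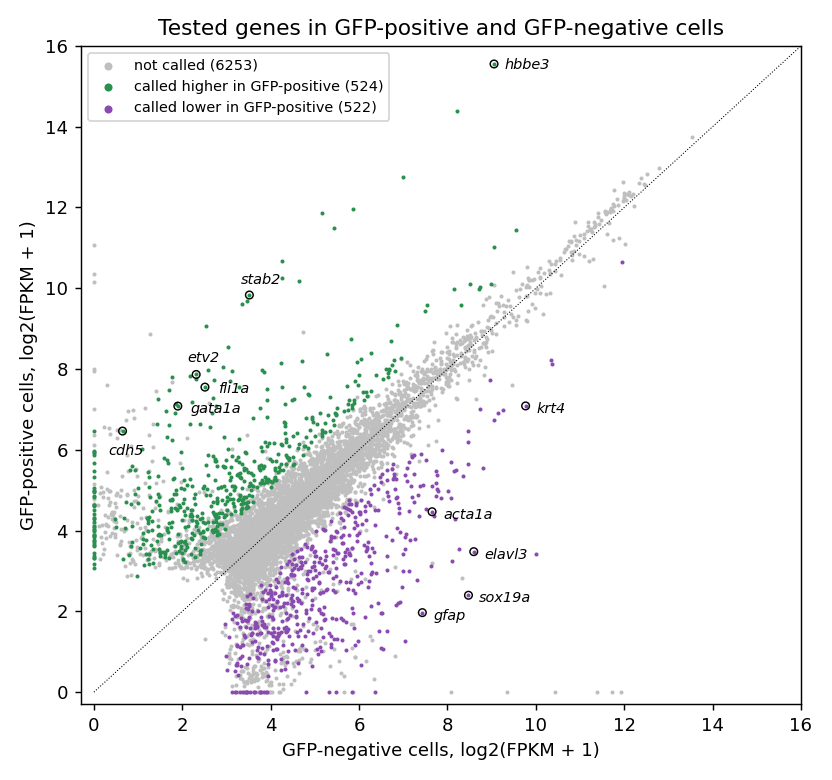
Group FPKM values of the 7299 tested genes, with GFP-negative cells on the x axis and GFP-positive cells on the y axis, both as log2(FPKM + 1). Green points are the 524 genes called higher and purple points the 522 genes called lower in GFP-positive cells, grey points were not called, and the dotted line marks equal values.

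The gene whose regulatory sequence drives the transgene, fli1a (ENSDARG00000054632; chromosome 18, 46987626 to 47051487 in the Zv9 build), stood at 187 FPKM in GFP-positive and 4.71 FPKM in GFP-negative cells. That is a 39.6-fold difference in the authors' deposited table, with a q of 0.000958. Because the cells were sorted on this transgene, the difference describes the sort. Genes with the largest increases, ranked by log2((FPKM + 1) ratio) among called genes, included several globins and stab2. Embryonic beta-globin hbbe3 (chromosome 12, 21691905 to 21693036) had 48081 FPKM in GFP-positive against 531 FPKM in GFP-negative cells. The alpha-globin hbae3 had 21440 against 298 FPKM. Globins are a multigene family whose reads can be shared among copies, so the division among hbbe1.2, hbbe2, hbbe3, hbae3 and the rows named hbae1 is uncertain. The scavenger receptor stab2 (chromosome 4, 9786318 to 9828071), found on venous endothelium, had 911 against 10.5 FPKM. The water channels aqp8a.1 and aqp1a.1 had 531 against 4.82 FPKM and 825 against 10.1 FPKM, and the red cell carbonic anhydrase cahz had 222 against 2.40 FPKM. Folds of these genes in the authors' deposited table ran from 68.4 for one hbae1 row to 110.2 for aqp8a.1. The ranking adds 1 FPKM to each value, and a gene with a low GFP-negative value can have a larger fold without it, as cdh5 does at 154 in the authors' deposited table. The uncharacterised si:ch211-214p16.2 had 88.1 FPKM in GFP-positive cells and was listed at 0 in GFP-negative cells. Another uncharacterised gene, si:ch211-5k11.12, had 787 against 9.21 FPKM and lies in the same Cuffdiff locus as hbae3.

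At the other end of this ranking, the genes with the largest decreases included sox19a and gfap of the neural list. The progenitor transcription factor sox19a had 4.27 FPKM in GFP-positive and 355 FPKM in GFP-negative cells. The glial filament gene gfap had 2.91 against 172 FPKM, the myelin protein gene plp1a 1.11 against 92.4 FPKM, and the Notch ligand gene dlb 1.85 against 98.2 FPKM. The transcription factor genes pou3f1 and rfx4 had 1.12 against 89.6 FPKM and 0.598 against 65.1 FPKM. The parathyroid hormone gene pth1a, the growth factor binding protein gene FGFBP3, the microRNA gene dre-mir-219-2 and the unnamed gene CR848045.1 were listed at 0 in GFP-positive cells, with 56.2, 39.1, 43.8 and 81.8 FPKM in GFP-negative cells. The uncharacterised si:ch73-21g5.7 and si:ch211-251b21.1 had 9.67 against 1027 FPKM and 1.42 against 130 FPKM. Among those with values above 0 in both fractions, folds in the authors' deposited table ran from 53.1 for dlb to 109 for rfx4.

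Markers shared by endothelial cells were higher in GFP-positive cells. Of 32 pan-endothelial genes tested, 18 were called higher, none lower, and 14 did not pass. Adjusted over the list alone, 23 were called higher. The list held more genes called higher than other tested genes did (two-sided Fisher's exact test, adjusted p = 2.98e-12), and 30 of its 32 members had the larger value in GFP-positive cells. The median log2((FPKM + 1) ratio) of GFP-positive over GFP-negative cells was 4.38, above each of 10000 random lists matched on expression. The vascular cadherin gene cdh5 (chromosome 7, 45433469 to 45577185) had 87.3 against 0.567 FPKM, with a q of 0.0303 in the authors' deposited table. The transcription factor gene etv2, a regulator of the earliest endothelial and blood progenitors (chromosome 16, 44778272 to 44783318), had 232 against 3.97 FPKM. The transcriptional cofactor gene lmo2 had 97.7 against 2.27 FPKM. Endothelial and hematopoietic transcription factors followed the same direction, with 15 of 20 called higher, none lower and 5 not passing, and 15 higher adjusted over the list alone (Fisher's exact adjusted p = 6.67e-13; median log2 ratio 2.40, above each random list; 18 of 20 larger in GFP-positive cells). Among them fli1b had 44.2 against 0.769 FPKM and tal1, a regulator of blood and vessel progenitors, had 93.7 against 5.22 FPKM. Of these 20 genes, 10 also belong to another of the lists.

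Receptors and subtype markers were divided. Of 19 vascular growth factor and guidance receptor genes, 8 were called higher, 1 lower and 10 did not pass, and adjusted over the list alone 10 were higher and 1 lower (Fisher's exact adjusted p = 0.000131 for genes called higher; median log2 ratio 1.1, above each random list; 14 of 19 larger in GFP-positive cells). At a q of 0.01, 5 were called higher. The vascular endothelial growth factor receptor genes kdrl (chromosome 14, 33838842 to 33899405) and flt4 had 52.4 against 2.13 FPKM and 44.3 against 0.898 FPKM. The angiopoietin receptor gene tek had 18.9 against 0.606 FPKM. The netrin receptor gene unc5b was called lower, with 2.44 against 9.73 FPKM. Of 13 venous and lymphatic genes, 6 were called higher, 1 lower and 6 did not pass, and adjusted over the list alone 7 were higher and 2 lower (Fisher's exact adjusted p = 0.000564; median log2 ratio 1.1, percentile 99.99 among random lists; 9 of 13 larger in GFP-positive cells). With list symbols matched to reference names alone, which loses members by spelling and lowered the called counts of several lists by over 1.5 times, this median was 4.58. Besides stab2, the hyaluronan receptor gene lyve1b had 59.7 FPKM and was listed at 0 in GFP-negative cells, and the endocytic adaptor gene dab2 had 154 against 5.44 FPKM. The lymphatic transcription factor gene prox1a was called lower, with 1.88 against 19.6 FPKM.

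Arterial and Notch pathway genes went both ways. Of 16 tested, 4 were called higher, 5 lower and 7 did not pass, and the counts were also 4 and 5 adjusted over the list alone. Fisher's exact test gave adjusted p = 0.0590 for genes called higher and adjusted p = 0.0116 for genes called lower. The median log2 ratio was 0.03, at percentile 45.8 of the random lists, and 9 of 16 had the larger value in GFP-positive cells. The arterial Notch ligand gene dll4 had 28.9 against 2.64 FPKM and the chemokine receptor gene cxcr4a 49.5 against 9.21 FPKM. In the other direction, dlb fell as given above, the Notch ligand gene jag1a had 0.727 against 14.4 FPKM, and the receptor gene notch1b had 8.92 against 33.5 FPKM. The list holds general Notch pathway genes beside arterial markers, so its counts do not describe arterial genes alone.

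Blood genes were among those most separated between the fractions. Of 24 erythroid genes, 22 were called higher, none lower and 2 did not pass, with 22 higher adjusted over the list alone (Fisher's exact adjusted p = 2.27e-22; median log2 ratio 5.24, above each random list; 24 of 24 larger in GFP-positive cells). The erythroid transcription factor gene gata1a (chromosome 11, 26344511 to 26352415) had 134 against 2.73 FPKM. The 10 globin rows made up 11.1% of the summed FPKM of GFP-positive cells and 0.167% of that of GFP-negative cells. Of 20 myeloid and pan-leukocyte genes, 8 were called higher, none lower and 12 did not pass, with 9 higher adjusted over the list alone (Fisher's exact adjusted p = 0.000182; median log2 ratio 3.92, above each random list; 20 of 20 larger in GFP-positive cells). The neutrophil peroxidase gene mpx had 63.6 against 1.11 FPKM. The macrophage gene mpeg1, the phosphatase gene ptpn6 and havcr1 had 21.7, 32.1 and 49.8 FPKM in GFP-positive cells and were listed at 0 in GFP-negative cells. Like all tested genes at 0 in a fraction, these genes have a p-value but no test statistic. The myeloid transcription factor gene spi1b had 43 against 0.232 FPKM but did not pass, with a q of 0.115 in the authors' deposited table.

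Neural crest and pharyngeal arch genes went both ways. Of 24 tested, 8 were called higher, 3 lower and 13 did not pass, and adjusted over the list alone 12 were higher and 3 lower (Fisher's exact adjusted p = 0.000615 for genes called higher; median log2 ratio 1.19, above each random list; 16 of 24 larger in GFP-positive cells). At a q of 0.01, 4 were called higher. Among the genes called higher, the homeobox gene alx1 had 21.5 against 1.5 FPKM, prrx1b 46.3 against 6.86 FPKM and dlx2a 75.9 against 19.3 FPKM. The endothelin receptor gene ednraa had 21.9 against 2.67 FPKM. The crest regulator genes sox9b and sox10 were lower, with 3.18 against 33.0 FPKM and 1.78 against 10.9 FPKM.

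Genes of the nervous system were lower in GFP-positive cells. Of 33 neural genes, 24 were called lower, none higher and 9 did not pass, with 28 lower adjusted over the list alone (Fisher's exact adjusted p = 5.70e-20). The median log2 ratio was -3.89, below each random list, and 33 of 33 members had the lower value in GFP-positive cells. The neuronal RNA-binding protein gene elavl3 (chromosome 3, 46836623 to 46855969) had 10.1 against 386 FPKM and the radial glia gene fabp7a 8.57 against 275 FPKM. The progenitor gene sox2 had 5.08 against 73.0 FPKM. Skeletal muscle genes were lower too, with 28 of 35 called lower, none higher and 7 not passing, and 32 lower adjusted over the list alone (Fisher's exact adjusted p = 7.42e-25; median log2 ratio -2.27, below each random list; 35 of 35 lower). The muscle transcription factor gene myog had 3.38 against 75.8 FPKM, and the sarcomeric actin genes acta1a and actc1a had 21.1 against 200.2 FPKM and 14.0 against 133 FPKM. The muscle chaperone gene hsp90aa1.1 had 9.77 against 126 FPKM. The myogenic gene myod1 had 1.31 against 36.7 FPKM and did not pass, with a q of 0.0837 in the authors' deposited table. In a typical member, the GFP-positive value was 4.08% of the GFP-negative value for neural genes and 17.4% for muscle genes (medians over the lists).

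Other tissues of the trunk and skin were also lower. Of 9 notochord and floor plate genes, 6 were called lower, none higher and 3 did not pass, with 7 lower adjusted over the list alone and 3 lower at a q of 0.01 (Fisher's exact adjusted p = 5.44e-05; median log2 ratio -2.37, percentile 0.03; 8 of 9 lower). The signalling gene shha had 1.13 against 13.1 FPKM, the cilia regulator gene foxj1a 0.799 against 12.2 FPKM and the collagen gene col8a1a 1.26 against 18.4 FPKM. Of 24 epidermal genes, 12 were called lower, 2 higher and 10 did not pass, and adjusted over the list alone 15 were lower and 2 higher (Fisher's exact adjusted p = 1.35e-07 for genes called lower; median log2 ratio -1.90, below each random list; 20 of 24 lower). The keratin genes krt4 and krt5 had 135 against 872 FPKM and 15.8 against 116 FPKM, agr2, a gene of secretory cells, had 6.59 against 76.5 FPKM, and the claudin gene cldne had 4.73 against 37.3 FPKM. The simple-epithelium keratin genes krt18 and krt8 were higher, with 1109 against 361 FPKM and 1052 against 423 FPKM. Keratins are a multigene family, so reads can be shared among them. Of 11 pigment cell genes, 6 were called lower, none higher and 5 did not pass, with 8 lower adjusted over the list alone (Fisher's exact adjusted p = 0.000185; median log2 ratio -2.21, percentile 0.07; 11 of 11 lower). The pteridine enzyme gene gch2 had 27.0 against 230 FPKM, trpm1b 3.06 against 33.2 FPKM and the melanin enzyme gene tyrp1b 2.51 against 19.6 FPKM. The transcription factor gene pax7a had 14.1 FPKM in GFP-negative cells and was listed at 0 in GFP-positive cells.

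**Figure D2:**
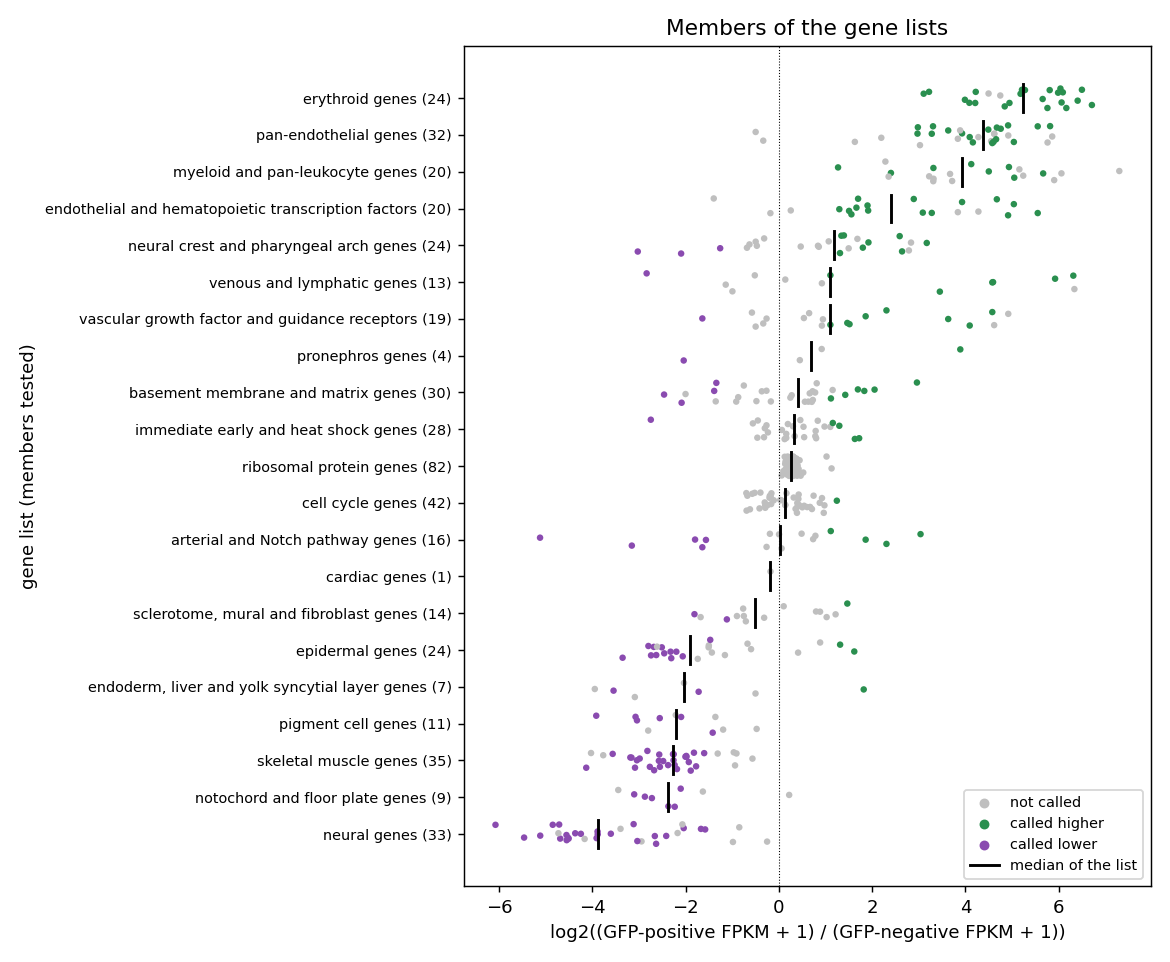
Members of the 21 gene lists with tested genes, with the log2 ratio of GFP-positive over GFP-negative FPKM (1 added to each value) on the x axis and the lists on the y axis, with the number tested in brackets. Each point is a gene, green if called higher, purple if called lower and grey if not called, and the black bars mark list medians, which run from -3.89 for neural genes to 5.24 for erythroid genes.

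Extracellular matrix, mesenchymal and organ lists showed smaller or mixed differences. Of 30 basement membrane and matrix genes, 6 were called higher, 4 lower and 20 did not pass, and adjusted over the list alone 7 were higher and 7 lower. Fisher's exact test gave adjusted p = 0.0471 for genes called higher and adjusted p = 0.307 for genes called lower. The median log2 ratio was 0.42, at percentile 99.5 of the random lists, and 17 of 30 were larger in GFP-positive cells. With genes alone in their Cuffdiff locus this median was 0.25, at percentile 91.1. The link protein gene hapln1b had 51.9 against 5.80 FPKM and the matrix metalloproteinase gene mmp14b 36.3 against 9.48 FPKM, while the basement membrane genes col18a1 and nid1a were lower, with 11.5 against 67.6 FPKM and 3.63 against 18.7 FPKM. Of 14 sclerotome, mural and fibroblast genes, 1 was called higher, 2 lower and 11 did not pass, with the same counts adjusted over the list alone (Fisher's exact adjusted p = 0.397 for genes called lower; median log2 ratio -0.51, percentile 0.31; 8 of 14 lower). With genes alone in their Cuffdiff locus this median was 0.24. The platelet-derived growth factor receptor gene pdgfra had 150.0 against 53.6 FPKM, and meox1 and the collagen gene col1a1b were lower, with 16.7 against 61.2 FPKM and 49.2 against 108 FPKM. Of 7 endoderm, liver and yolk syncytial layer genes, 1 was called higher, 2 lower and 4 did not pass, with the same counts adjusted over the list alone (Fisher's exact adjusted p = 0.186 for genes called lower; median log2 ratio -2.04, percentile 0.05; 6 of 7 lower). The carboxypeptidase gene cpn1 had 84.6 against 23.3 FPKM, and onecut1 and the apolipoprotein gene apoc1l had 2.01 against 34.1 FPKM and 128 against 424 FPKM. Of 4 pronephros genes, slc20a1a was called higher with 39.6 against 1.74 FPKM, pax2a was called lower with 2.38 against 12.9 FPKM, and 2 did not pass. Adjusted over the list alone, 2 of these 4 were higher and 1 lower (Fisher's exact adjusted p = 0.397 in either direction; median log2 ratio 0.68, percentile 91.3; 3 of 4 larger in GFP-positive cells). A single cardiac gene was tested and was not called (log2 ratio -0.18, percentile 35.3; Fisher's exact adjusted p = 1 in either direction).

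Cell cycle, stress response and ribosomal protein genes made up the remaining lists. Of 42 cell cycle genes, 1 was called higher and none lower, and 41 did not pass, with 0 called adjusted over the list alone (Fisher's exact adjusted p = 0.524 for genes called higher; median log2 ratio 0.14, percentile 72.3; 24 of 42 larger in GFP-positive cells). At p under 0.05 without adjustment, 4 were higher and 0 lower in the authors' deposited table. With genes alone in their Cuffdiff locus the cell cycle median was 0.39, at percentile 99.1. The called gene, the mitotic kinase gene cdk1, had 127 against 52.9 FPKM. Of 28 immediate early and heat shock genes, 4 were called higher, 1 lower and 23 did not pass, and adjusted over the list alone 5 were higher and 1 lower (Fisher's exact adjusted p = 0.289 for genes called higher; median log2 ratio 0.32, percentile 97.9; 20 of 28 larger in GFP-positive cells). At a q of 0.01, 2 were called higher, and against random lists not matched on expression the percentile was 97.3. The cytokine signalling inhibitor gene socs3a had 194 against 61.9 FPKM, the AP-1 gene fosl2 58.5 against 17.0 FPKM and klf6a 123 against 49.4 FPKM. The small heat shock protein gene hspb1 was lower, with 13.6 against 97.1 FPKM. Of 82 ribosomal protein genes, 0 were called by the Cuffdiff test, with 0 adjusted over the list alone and 1 higher at p under 0.05 without adjustment in the authors' deposited table. All 82 had the larger value in GFP-positive cells (median log2 ratio 0.27, percentile 98.7; Fisher's exact adjusted p = 0.0116 for fewer calls than other tested genes, in either direction). The matched random lists had a median of 0.18, so part of this shift was shared with genes of similar expression. With ribosomal protein genes alone in their Cuffdiff locus the percentile was 97.0. No gene name in the table carried the prefix of mitochondrially encoded genes, so that list has no values.

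A q above 0.05 did not always mean a small difference. Of 423 tested genes with at least 10 FPKM in one fraction and at least a 16-fold lower value in the other, 235 were not called in the authors' deposited table, 119 of them higher in GFP-positive and 116 higher in GFP-negative cells. The share called differed with the lower value, and the level in the higher fraction differed with it. It was 5 of 99 genes with a lower value above 0 and up to 0.5 FPKM, and 35 of 39 genes with a lower value over 5 FPKM, where the median values in the higher fraction were 16.6 and 275 FPKM. Where the lower value was exactly 0, 51 of 87 were called. Members of the lists with such a difference and no call numbered 28 genes, in 10 of the 22 lists, with 9 each among pan-endothelial and myeloid genes, spi1b among the latter.

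**Figure D3:**
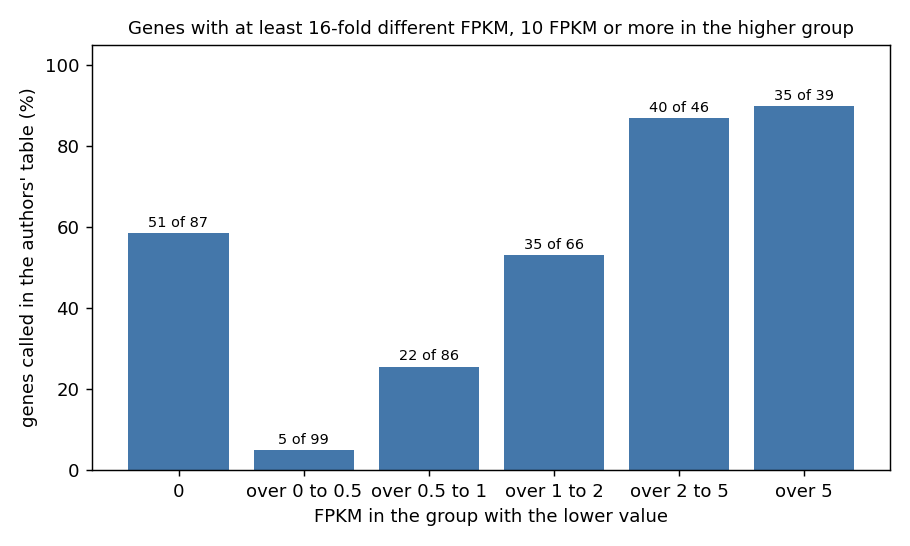
Share of the 423 tested genes with at least 10 FPKM in one fraction and at least a 16-fold lower value in the other that were called in the authors' table, on the y axis in percent, by the FPKM of the lower fraction on the x axis. Numbers above the bars give called genes and all genes; the share is 5 of 99 just above 0 and 35 of 39 over 5 FPKM.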

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

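All tests in this part were chosen after the values were seen. Signals in genes that Cuffdiff did not test stand outside the comparison above. Of these genes, 140 had at least 5 FPKM in GFP-positive cells and at most 1 part in 8 of that in GFP-negative cells, and 203 had the reverse. In the first set 84 were listed at 0 in the other fraction, in the second set 70. The sets hold vessel, blood, muscle and neural genes among others, and the examples were named after their values were seen. The microRNA gene dre-mir-126a, whose host gene is endothelial, had 179 FPKM in GFP-positive cells and was listed at 0 in GFP-negative cells. The leukocyte genes lcp1 and cxcr3.2 had 10.7 and 11.0 FPKM and were also listed at 0 in GFP-negative cells, as was the endothelial gene ecscr with 6.86 FPKM. The scavenger receptor gene stab1 had 5.31 against 0.107 FPKM. The muscle microRNA gene dre-mir-133b had 179 FPKM in GFP-negative cells and was listed at 0 in GFP-positive cells. Small RNA names account for 24 genes in each set, and rows of the same small nucleolar RNA name went both ways: one SNORD52 row had 2223 FPKM in GFP-positive cells and was listed at 0 in GFP-negative cells, and another had 671 FPKM in GFP-negative cells and was listed at 0 in GFP-positive cells. None of these differences has a test.

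The first pattern is that 235 of 423 genes with a 16-fold or larger difference were not called in the authors' deposited table. Among genes above 0, calls were more frequent at a lower value over 0.5 to 1 FPKM than at or below 0.5 FPKM (22 of 86 against 5 of 99; Fisher's exact p = 0.000103), consistent with few fragments in the lower fraction limiting the test. A lower level in the higher fraction is argued against as the whole cause for these genes, since among genes of 16 to 32 FPKM there 12 of 42 against 3 of 44 were called (Fisher's exact p = 0.0102). Of the genes at exactly 0, 51 of 87 were called (Fisher's exact p = 2.4e-16 against 5 of 99), which does not measure the effect of few fragments there, because 100% of tested genes at 0 lack a test statistic and 0% of the others do. A candidate explanation is that exact zeros are tested in another way. Spread between the libraries stays open too, because the table has 1 value per group, and no biological explanation was tested. Genes sharing a Cuffdiff locus with another gene were not set apart in these comparisons. Over all tested genes, 176 of 1757 such genes were called, against 1046 of 7299 in all. Whether a shared locus limited the calls was not tested.

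The second pattern is that muscle and epidermal genes kept more of their GFP-negative level in GFP-positive cells than neural genes did. Median log2 ratios were 1.61 larger for muscle and 1.98 larger for epidermal than for neural genes (permutation p = 2e-05 and p = 4e-05; adjusted p = 4e-05 for both by permutation), which argues against even carry-over of GFP-negative cells as the whole cause. An added source of muscle RNA of constant make-up, such as broken fibres, would keep muscle ratios alike. The SD of the log2 ratio was 0.86 for muscle and 0.52 for cell cycle genes (permutation p = 0.00433), but the median value in the lower fraction was 15.8 FPKM for muscle and 53.5 FPKM for cell cycle genes, so noise at low values cannot be told apart from a real spread and this source stays open. Low expression of some muscle genes in GFP-positive cells stays open as well, untested. In the epidermal list, 20 of 24 genes had the lower value in GFP-positive cells and 4 the larger, with krt18 and krt8 called higher. Expression of epidermal genes by GFP-positive cells can therefore enter the epidermal median, and its part in the difference was not tested.

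The third pattern is that blood genes, and 8 of 24 crest and arch genes against 3 called lower, were higher in a fraction labelled endothelial. Even carry-over of GFP-negative cells into it cannot lift a gene above its GFP-negative level. The pattern itself, without a further test, argues against even carry-over for blood genes. All 44 tested erythroid and myeloid genes were larger in GFP-positive cells, with a median ratio of 67.6. Members listed at 0 in GFP-negative cells, such as mpeg1, have no finite ratio, so this median depends on how they are counted. With 1 FPKM added to each value, median log2 ratios were 5.24 for erythroid and 3.92 for myeloid genes. Entry of some GFP-negative cell types in preference to others could give such ratios and stays open. Their most abundant members, hbbe3 and hbae3, had 48081 and 21440 FPKM there. Transgene activity in blood cells, some crest or arch cells, or their precursors, and autofluorescent cells in the sort gate, are both candidate explanations that these values leave open.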

How the results depend on the processing

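No paired analysis was possible because the table has 1 value per gene and group, although the replicate numbers 1 and 2 recur in both groups. For the same reason a replicate block, leaving out each replicate, a per-sample pseudocount of 0.1, a camera test and other count or per-sample models were not run, and no result shows how far it rests on 1 library. Depth is unknown, so what it limits cannot be stated. The counts of called genes stayed within 1.5 times the main value in 24 of 27 alternatives. The exceptions were those at a q of 0.01, with 630 genes, 301 higher and 329 lower, as fewer genes pass a stricter threshold. A minimum log2 ratio of 1, minimum values of 1 and 5 FPKM, BH again and centring left all 1046 calls in place. Those settings removed no gene and so say little about how stable the calls are. Counts per list stayed within 1.5 times the main value in 125 of 147 alternatives. The minimum of 1 FPKM and centring could not change these counts either, because they removed no called gene. At a q of 0.01, 5 growth factor and guidance receptor genes, 4 crest and arch genes, 2 immediate early genes, 0 pronephros genes and 0 cell cycle genes were called higher, and 3 notochord genes and 1 sclerotome gene lower. With first symbols alone, 1 endoderm gene was called lower. The other exceptions came from an alternative chosen after seeing the data, list symbols matched to the reference's names alone, which drops members spelled otherwise there. It left 11 pan-endothelial genes, 4 transcription factors, 3 myeloid, 3 crest and arch, 1 matrix and 0 pronephros, cell cycle or immediate early genes called higher, and 13 muscle, 7 neural, 3 notochord, 3 pigment, 3 arterial and 0 sclerotome genes called lower. Cardiac and pronephros genes had no member under it. Matching by either name, also chosen afterwards, gained 25 members and left every list count within 1.5 times. List medians changed sign in 4 of 187 alternatives: the sclerotome median was 0.24 with genes alone in their locus (chosen after seeing the data; the cause was not tested) and 0.88 with reference names alone, which also gave -0.17 for matrix and -0.056 for immediate early genes and moved the venous median from 1.1 to 4.58. A further 4 medians kept their sign but came within percentiles 2.5 to 97.5: matrix (0.25, percentile 91.1) and ribosomal genes (0.28, 97.0) alone in their locus, and immediate early genes against random lists not matched (97.3) or matched by either name (97.0). Moved outside them were cell cycle genes alone in their locus (0.39, 99.1). The 280 alternatives of named genes' log2 ratios, with a pseudocount of 0.1, as deposited or centred, kept their sign for called genes. That outcome was fixed, because a pseudocount or the deposited ratio cannot change a sign. Centring moved ratios by only 0.01, and called genes had absolute log2 ratios of at least 1.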

Other observations

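The groups of genes and the tests in this part were chosen after the values were seen, so they are hypotheses from the same data; 4 groups were tested, with BH over them. Enzymes of heme synthesis were higher in GFP-positive cells: 9 of 10 were called higher and 0 lower (Fisher's exact adjusted p = 1.78e-09; median log2 ratio 4.22). Of the 9, 2 also belong to the erythroid list, so this partly repeats that list's result. The erythroid aminolevulinate synthase gene alas2 had 98.1 against 1.67 FPKM, urod 265 against 6.63 FPKM and fech, which inserts the iron, 54.9 against 2.02 FPKM. The housekeeping form alas1 had 14.4 against 11.77 FPKM and was not called. Of 27 tested genes of the clathrin adaptor (AP) complexes and sorting nexins, which move receptors through endosomes, 11 were called higher and 0 lower (Fisher's exact adjusted p = 1.06e-06; median log2 ratio 0.91). Among them ap2m1a had 546 against 116 FPKM, snx3 230 against 63.3 FPKM and snx5 111 against 14.0 FPKM.

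Hox genes, which mark position along the body axis, were called lower in 17 of 43 cases and higher in 0 (Fisher's exact adjusted p = 3.8e-09; median log2 ratio -2.27). The levels of hoxb1b were 13.4 against 130 FPKM, of hoxa3a 22.2 against 183 FPKM and of hoxb9a 37.5 against 114 FPKM. Some Hox genes share a Cuffdiff locus, as do hoxc3a, called lower, and hoxc4a, not called (chromosome 23, 36132968 to 36328653). The uncalled hoxc4a had 0.711 against 16.2 FPKM, so lack of a call did not mean equal levels. Fisher's exact test counts such neighbours as separate genes, and the effect of shared loci was not tested. Hedgehog pathway genes were called lower in 8 of 13 cases and higher in 0 (Fisher's exact adjusted p = 8.09e-07; median log2 ratio -1.11). These include the pathway's target genes ptch1, with 4.58 against 15.1 FPKM, and hhip, with 10.7 against 29.0 FPKM. The ligand gene shha belongs to this group and to the notochord list.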
